A study of Homo sapiens with 9 samples.

How the data were processed

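The 9 libraries are guide counts from genome-wide CRISPR interference screens in SU-DHL-1 cells, 1 library per group and 9 groups. Per the labels' protocols, the guide library was introduced with about 0.3 viral particles per cell intended, cells were selected in puromycin for 7 days, and drugs were given in pulses. Per the labels' protocols, the pulses were set to reduce growth 28-fold to 210-fold against DMSO, with 40% to 60% of the cells killed by each. Guides were amplified from 400 µg of genomic DNA in 60 to 84 reactions and sequenced at a minimum of 200x coverage, per the labels' protocols. The labels name more than 1 culture medium, so the medium is not stated here.

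The deposited values are 5 gene tables, 1 per drug. Per the file headers, each gene has a p-value from a Mann-Whitney test of its guides, a phenotype score that averages its strongest 3 guides, and the number of guides behind each, for untreated against T0, treated against untreated and treated against T0. The authors' tables also hold pseudogenes, which are sets of non-targeting guides treated as genes, different in each table. The pralatrexate and romidepsin tables hold, per the file headers, the product of -log10 of the p-value and the absolute phenotype; recomputed here, it differed by at most 0.000128 and 1.26e-06. The scale of the phenotype, any division by cell doublings, the normalisation and the software used for counting are not given in the sources used here. For that reason sizes were compared within a drug only. Read counts, depth per library and values per guide are not in the gene tables, so no test was refitted and no interval on counts was computed. The spread behind each p-value is the spread between guides in 1 pair of libraries, and it holds no error between cultures.

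The gemcitabine table has 41052 lines (20526 of genes, with several promoters for some) and each of the others has 37810 lines (18905 of genes). One value per gene was kept, the lowest p-value over promoters as the authors' tables give it. Untreated growth values of screen 1 were the same in the gemcitabine and oxaliplatin tables (largest difference 0 over 18901 genes). Names were matched to RefSeq (GRCh38.p14) for current symbols and for which genes neighbour each other, and no coordinates were used otherwise. Of 18901 library genes, 1461 names were not current symbols and 1269 of those matched a synonym. Among the names that were not current, 24 had been turned into dates in the deposited tables and were left out of the named genes.

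The authors' p-values were adjusted here by the Benjamini-Hochberg method over all targeted genes with a value, and an adjusted p under 0.05 was the planned call. A score of 7 or more was an alternative, where the score is the phenotype over the SD of the pseudogene phenotypes, times -log10 p. With 5 guides, the usual number, the smallest p that a Mann-Whitney test in its normal approximation can give is 0.000108. A gene at that p passes the adjusted threshold only if 41 genes reach it or a lower p. Genes with more guides can reach a lower p. The adjusted p called 0 genes in 4 drugs and 1 under bortezomib, and 1739, 1329, 1919, 1494 and 1778 genes had an unadjusted p under 0.05 under gemcitabine, oxaliplatin, pralatrexate, romidepsin and bortezomib. Those are 9.25%, 7.08%, 10.2%, 7.95% and 9.42% of the genes, against 5.16%, 4.93%, 5.01%, 5.06% and 5.07% of the pseudogenes. The score of 7 therefore leads the description of genes. That choice was made after these counts had been seen, together with those at an adjusted p under 0.10, at a score set to a 5% pseudogene rate and against T0. At the score of 7, the rate in pseudogenes was 5.03%, 7.37%, 5.37%, 11.0% and 7.87% of that in genes, in the same order of drugs. Pseudogenes had fewer guides: under gemcitabine 11014 of 18887 had 5 or more, against 14721 of 18790 genes. In every drug, pseudogenes with 5 or more guides passed more often than pseudogenes as a whole. These rates, and a score set to a 5% pseudogene rate, may therefore understate false calls among genes with 5 or more guides. The score can be reached by a large phenotype alone: 6, 6, 8, 5 and 9 of the called genes had an unadjusted p over 0.05, and 4, 4, 6, 4 and 7 of these rest on 1 guide.

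The procedure was tested on simulated data, with guide values drawn from a normal distribution and the real number of guides of each gene. Every guide of a changed gene was given the same shift. Guides of unequal strength were not simulated, so recovery in the real data may be lower. With 100 genes shifted by 2 and 100 by 4 control SDs, the adjusted p recovered 0 in every drug. In that test the score of 7 recovered 95%, 95%, 97%, 96% and 99% of the genes shifted by 4, and 45%, 36%, 23%, 40% and 37% of those shifted by 2, with 11, 7, 11, 23 and 15 false calls. A second mix was added after that result, with 60 genes shifted by 2, 60 by 4 and 80 by 8. There the adjusted p recovered 73.8%, 81.3%, 83.8%, 77.5% and 87.5% of the genes shifted by 8, with 0 false calls.

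The comparisons, the adjusted p, the gene lists, the rule for named genes and the alternatives stated as planned were chosen before the data were examined. Under that rule the named genes are, per drug, the 10 highest and 10 lowest called genes and the called members of the drug's own pharmacology list. For the lists of other drugs they are the 2 to 4 largest called members, and for growth the 10 lowest and 5 highest. DCK, RRM1, ERCC1, SLFN11, SLC19A1, FPGS, HDAC1, HDAC2, HDAC3, ABCB1, PSMB5 and PSMD1 are always given. Some genes that the rule names, and 1 gene list, are not reported here. Genes called the same way in 3 or more drugs are named up to 10 per direction, by the mean of their values, which serves to choose names and is not given as a size; their calls at a 5% pseudogene rate were added after the data had been seen. Since the adjusted p called almost nothing, the rule was applied to the calls at the score of 7, and 127 of the 136 named pairs of gene and drug pass it. A few list members beyond the rule, FAM136A, RBM4 and genes in the closing part were named after their values were seen.

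There were 30 gene lists, with 746 of their 747 members in the library. They cover gemcitabine pharmacology, antifolate pharmacology, histone deacetylase complexes, ABC transporters, nucleotide excision repair, the Fanconi anaemia pathway, homologous recombination, translesion synthesis, base excision repair, mismatch repair, the replication checkpoint and apoptosis. Others cover the 20S and 19S proteasome, proteasome stress and chaperones, the unfolded protein and integrated stress responses, ALK and STAT3 signalling, mTORC1, cullin ligases, G1/S control, Mediator, SWI/SNF, mitochondrial complex I, the mitochondrial and cytosolic ribosomes, iron and glutathione, pyrimidine and purine synthesis, Schlafen and platinum transport genes, and olfactory receptors as a control. For each list and drug, the median was placed among 10000 random lists of the same size, matched on decile of the untreated growth phenotype. This percentile describes these libraries and is not a p-value. The lowest growth decile spans a wide range, so the percentile was also computed after a lowess fit (fraction 0.3) of the drug phenotype on growth was subtracted, a step added after the data had been seen. Scores after this removal use the corrected phenotype over the SD of the corrected pseudogene phenotypes. The authors' p-value in these scores was left unchanged. Another 7 lists were written after the top genes had been seen, and only their unseen members were tested, 1 of the lists under 2 drugs.

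Alternatives were adjusted p under 0.01 and 0.10, the score of 7, a score at a 5% pseudogene rate, an added minimum of 2 control SDs, p times the number of promoters, treated against T0, centring on the median gene, the residual after growth, genes with the usual number of guides, unmatched random lists, and Spearman in place of Pearson. Overlaps between drugs are given beside the number that independent lists would share. Covariances are given beside those of the fixed olfactory receptors, since pseudogenes differ between tables, and beside those of all olfactory receptor genes, a comparison added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.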

Results

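The data came from pooled CRISPR interference screens in SU-DHL-1, a line of ALK-positive anaplastic large cell lymphoma grown in suspension. The cells carried dCas9-KRAB, which represses a gene at its promoter where a guide RNA directs it, and a genome-wide guide library. In screen 1, cells were given pulses of gemcitabine (20 nM), oxaliplatin (2 µM), pralatrexate (5 nM) or romidepsin (5 nM), or 0.1% DMSO, and were harvested at day 13. In screen 2, they were given pulses of bortezomib (10 nM), or 0.1% DMSO, and were harvested at day 14. Guides were counted by sequencing at the end and in a sample taken just before treatment (T0). There were 9 libraries in 9 groups, with 1 library per group and no replicates, so no value has an error between cultures. The 4 drugs of screen 1 share 1 T0 and 1 untreated library, and bortezomib has its own pair. The screens were sequenced at different facilities, so a difference between bortezomib and the other 4 drugs and a difference between the screens cannot be told apart; bortezomib against its own untreated cells lies within screen 2. Read depth per library is unknown, since the gene tables hold no counts; per the labels' protocols, sequencing had a minimum of 200x coverage.

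Each value below is the phenotype of a gene divided by the standard deviation (SD) of the phenotypes of control pseudogenes, which are sets of non-targeting guides, in the same table. It is given in control SDs. A gene called higher had guides that were more abundant in the treated than in the untreated library, and such guides can still have been depleted since T0. For some genes the value against T0 rests on another number of guides than the value against untreated cells, so a change of sign between them need not come from the same guides. A score is the value in control SDs times the -log10 of the p-value of the authors. Sizes are comparable within a drug and not between drugs. Identifiers are the gene symbols of the library, some of them older names.

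The first comparison set untreated cells against T0 and asked which genes the line needs for growth without drug. In screen 1, the lowest genes included CENPA, the histone that marks centromeres (-29.3 control SDs), TAF2 of the general transcription factor TFIID (-28.7) and TAMM41, an enzyme of mitochondrial cardiolipin synthesis (-28.1). RPP25L (-27.5), CDAN1 (-26.3), the mitochondrial ribosomal protein gene MRPS18A (-26.1) and NRDE2 (-25.9) followed, with C16orf59 at -28.1. The neighbours NOP10, which codes for a part of small nucleolar ribonucleoproteins, and NUTM1 had the same value, -26.0, and shared a value of -23.6 in screen 2. Their scores in screen 1 were identical too. Both names may therefore rest on the same guides, and NUTM1 cannot be read as a separate growth gene. In screen 2, GTF3C3 of the RNA polymerase III factor TFIIIC was lowest (-36.0), followed by RPP25L (-31.7), CENPA (-31.5), the nuclear NAD synthesis enzyme NMNAT1 (-30.1) and the replication fork protein gene TIMELESS (-30.0). CENPI (-29.6), TAMM41 (-29.6), SHFM1 (-29.4), KANSL2 (-29.1) and KANSL3 (-28.9) completed the 10 lowest. The highest were small by comparison: TRIM77 (2.45), IFI27L1 (2.13), NPHP4 (1.98), SNX33 (1.97) and MFN2 (1.95) in screen 1. In screen 2 they were the heme-regulated kinase gene EIF2AK1 (2.38), KIAA0141 (2.37), ESRRA (2.19), LRRC15 (2.13) and LARP4B (1.96). MFN2 stood at -7.17 in screen 2, where it did not pass the adjusted p.

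At a Benjamini-Hochberg adjusted p under 0.05, 845 of 18893 genes were lower and 6 higher in screen 1, and 1356 of 18901 were lower and 14 higher in screen 2. Of the genes lower in screen 1, 682 (80.7%) were also lower in screen 2, where independent lists would share 60.6. None was higher in both (0 genes), and 0 were called in opposite directions. Across genes, which are not independent replicates, the growth phenotypes of the screens had a Pearson r of 0.865 and a Spearman rho of 0.465. Over the genes lower in either screen, r was 0.798.

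**Figure D1:**
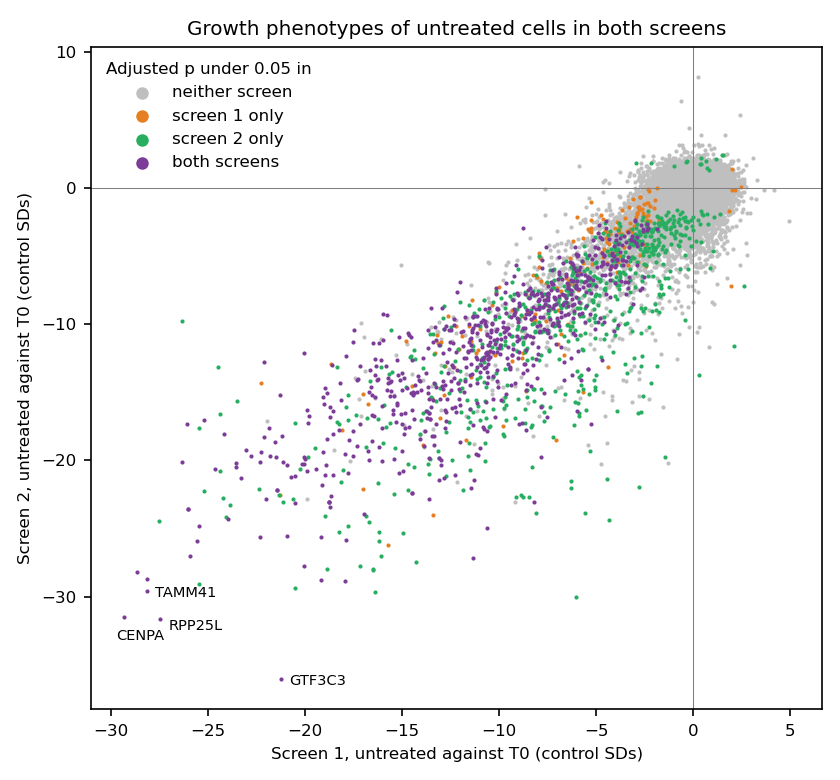
Growth phenotype of each gene in untreated cells against T0, screen 1 on the x axis and screen 2 on the y axis, both in control SDs, coloured by whether the gene passed an adjusted p under 0.05. The 682 genes lower in both screens lie along the diagonal at negative values.

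Under gemcitabine, a deoxycytidine analogue that must enter the cell and be phosphorylated, the highest gene was DCK (19.6 control SDs), whose kinase adds the first phosphate. CMPK1, which adds the second (12.4), and SLC29A1, the nucleoside importer (10.4), were also higher. So were SAMHD1, a deoxynucleotide triphosphate hydrolase (7.59), and DCTPP1, a pyrophosphatase of deoxycytidine triphosphate (6.36). SLFN11, which blocks stressed replication forks, stood at 11.6. The other 6 of the 10 highest were MEAF6 of the MYST acetyltransferase complexes (10.9), the glycolytic gene GPI (10.1), NFYC (9.50), ICT1 (12.2), MRPL22 (10.1) and TIMM44 (9.87). ICT1, MRPL22 and TIMM44, all of mitochondrial function, were lower against T0 at the score of 7, and ICT1 and MRPL22 rest on 1 guide each. Against T0, the values of ICT1 and MRPL22 rest on 4 and 5 guides.

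The lowest genes under gemcitabine were the transcription factor gene CEBPB (-10.7), RIF1, which controls replication timing and protects forks (-10.4), THRAP3 (-9.38) and MED12 of the Mediator kinase module (-9.36). INO80E (-8.03), CDADC1, a relative of cytidine deaminases (-7.92), and the uridine-cytidine kinase gene UCK2 (-7.44) followed. BCL2A1, an anti-apoptotic BCL2 relative (-7.37), and the helicase gene DHX36 (-7.30) were also among the lowest. The replication checkpoint genes HUS1 (-5.49), RAD9A (-4.04), ATR (-3.88) and CHEK1 (-3.60) were lower too. RRM1, which codes for a target of the drug, has no value against untreated cells; against T0 it stood at -9.46 on 1 guide (unadjusted p 0.0839), a value that includes growth, which was -5.64 in untreated cells.

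At a score of 7 or more, 233 of 18790 genes were higher and 123 lower under gemcitabine, against 18 of 18887 pseudogenes. At a Benjamini-Hochberg adjusted p under 0.05, 0 genes passed (smallest adjusted p 0.101), while 1739 passed an unadjusted p under 0.05. Of the higher calls, 103 changed sign when treated cells were compared with T0.

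Among the gene lists, the gemcitabine pharmacology list (19 genes measured) had 5 members higher and 0 lower at the score of 7, and 5 passed when adjusted over the list alone. Its median of 0.227 lay at percentile 76.7 of random lists matched on growth. The replication checkpoint list had a median of -1.25, at percentile 0.01, and 4 members lower adjusted over the list alone, with DBF4 (3.02) higher. The Mediator list, with 0 members higher and 6 lower at the score of 7, had a median of -1.65, below all 10000 random lists; adjusted over the list alone, 7 members were lower and CDK8 higher. SWI/SNF chromatin remodelling genes had a median of 1.32 (percentile 99.98), with SS18 called higher and 1 member passing adjusted over the list alone. G1/S cell cycle control (median 0.718, percentile 99.5) had TFDP1, CCNA2, E2F3 and E2F1 higher and CCNE2 lower; adjusted over the list alone, CDKN1A passed in place of CCNA2 among 4 higher, and CCNE2 and CCNE1 were lower. The cytosolic ribosome list (median 1.1, percentile 99.4) had RPS2 among its higher genes and 0 members adjusted over the list alone. Cullin ligases, neddylation and the COP9 signalosome had a median of -0.680 (percentile 0.09) with DCUN1D1 called higher, also when adjusted over the list alone. Mitochondrial complex I had a median of -0.529 (percentile 0.03) with 0 members called at the score of 7 and 0 adjusted over the list alone. Histone deacetylase complexes (median -0.649, percentile 0.08) had HDAC3 higher and HDAC2 and HDAC8 lower, with 0 adjusted over the list alone. Nucleotide excision repair (median 1.2, percentile 99.9) had GTF2H3 higher at the score of 7, and 5 members higher adjusted over the list alone. ABC transporters (median 0.861, percentile 98.6, and 96.2 after the growth trend was removed) had 0 called at the score of 7, and ABCB1 and ABCC11 higher adjusted over the list alone. Over all genes, 0 members of any of these lists passed.

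Oxaliplatin crosslinks DNA. Among genes of crosslink repair, BRIP1, a helicase of homologous recombination and the Fanconi anaemia pathway, stood at -7.84 control SDs and FANCD2, the protein that is ubiquitinated at crosslinks, at -7.73. UBE2T (-5.58), the partner of FANCD2 FANCI (-4.43) and FANCM (-2.88) were also lower, as were RAD51B (-4.60) and the translesion synthesis ligase gene RAD18 (-2.54). The checkpoint kinase gene ATR stood at -5.87 and its partner ATRIP at -3.22. RAD18 and ATRIP came to scores of -6.94 and -6.74 after the trend with growth was removed, a step that also subtracts the shift of the median gene. The other low genes were the splicing gene SF3B2 (-8.60), THOC6 of messenger RNA export (-7.82), RPL24 (-7.49), NMD3 (-7.31), SP110 (-7.06), the ubiquitin ligase adaptor gene SPOP (-6.96), HMG20B (-6.52) and PCED1A (-6.47). SF3B2, RPL24 and NMD3 rest on 1 guide each, and the near neighbour of PCED1A, VPS16, was called lower as well.

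Among the higher genes under oxaliplatin were the amino acid transporter gene SLC43A2 (6.07), BRD2 (4.53), MEAF6 (4.38) and KAT7, the acetyltransferase of a MEAF6 complex (4.07). DDA1 (4.39) and DET1 (3.73), both of a cullin 4 ubiquitin ligase, and the autophagy regulator gene AMBRA1 (3.64) were higher too. SARS (7.33, 1 guide) and HEATR1 (4.47, 2 guides) were higher than in untreated cells and lower against T0 at the score of 7, on 4 guides each. ERCC1, of nucleotide excision repair (-0.434), and SLFN11 (0.528) were not called.

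At a score of 7 or more, 17 of 18769 genes were higher and 118 lower, against 10 of 18876 pseudogenes. A share of 12.6% of the calls was higher, and 24.6% (32 higher, 98 lower) after the trend with growth was removed. Centring on the median gene, which lay at -0.219 control SDs, gave 21.5% (28 higher, 102 lower) with no correction for growth. Across genes, the Pearson r of the drug phenotype with the growth phenotype was 0.0226. Removal of the trend also subtracts the shift of the median gene, so the change in share need not come from growth. At an adjusted p under 0.05 by Benjamini-Hochberg, 0 genes passed (smallest 0.406), while 1329 passed an unadjusted p under 0.05.

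The Fanconi anaemia list had a median of -1.74 (percentile 0.01), with 0 members higher and 4 lower both at the score of 7 and adjusted over the list alone. Homologous recombination had a median of -1.19 (percentile 0.08), with BRIP1 and RAD51B lower at the score of 7 and BRIP1 and SWI5 lower adjusted over the list alone. Histone deacetylase complexes had a median of -0.902 (percentile 0.02) with 0 members called at the score of 7 and 0 adjusted over the list alone. Mitochondrial complex I had a median of -1.17 (percentile 0.05) with NDUFB11 and NDUFC1 lower, both also adjusted over the list alone. The replication checkpoint list lay at percentile 29.9, with ATR and ATRIP lower at the score of 7 and 0 members adjusted over the list alone. The mitochondrial ribosome (median -0.920, percentile 1.89) had MRPL1 lower and 0 adjusted over the list alone, and the antifolate list (median 0.390, percentile 98.7) had MTHFS lower by both criteria, including adjusted over the list alone. Translesion synthesis (percentile 21.9) had RAD18 lower at both the score of 7 and adjusted over the list alone. Nucleotide excision repair (median -0.425, percentile 28.2) and the Schlafen and platinum transport list (percentile 62.8) had 0 members called at the score of 7 and 0 adjusted over the list alone. Mismatch repair, with 8 genes, had 0 called by either criterion, including adjusted over the list alone, at percentile 81.5. Over all genes, 0 members of these lists passed.

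Pralatrexate is an antifolate that enters through the reduced folate carrier and is retained after polyglutamylation. The carrier gene SLC19A1 was the highest (23.8 control SDs), and FPGS, the polyglutamylating enzyme, was also higher (4.0). The folate-dependent purine synthesis gene GART (4.81) and MTHFD1, which interconverts folates (3.90), were higher, as was MTOR (9.52). The lowest genes were TK1, which codes for a thymidine kinase (-14.7), the nucleoside importer gene SLC29A1 (-10.7) and DUT, which codes for the deoxyuridine triphosphatase (-9.49). The base excision repair polymerase gene POLB (-6.78, unadjusted p 0.0662), APEX2 (-5.05) and MTHFS, which returns a stored folate to use (-4.08), were lower as well. MED12 (-8.49) and CCNC (-6.61) of the Mediator kinase module, RIF1 (-6.23), BCL2A1 (-5.96), OGFR (-6.65) and NKX6-1 (-6.18) completed the 10 lowest. AFMID, the near neighbour of TK1, was called lower with it. Some of these folate genes were also called the same way under other drugs. GART was higher under gemcitabine, and GART and MTHFD1 under romidepsin, where neither passes a score set to a 5% pseudogene rate. MTHFS was lower under oxaliplatin and bortezomib.

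Other high genes under pralatrexate were the remodeller gene EP400 (9.24), TAF2 (14.7), CDC20 of the anaphase-promoting complex (14.7), PITRM1 (9.84), EEF1E1 (9.83), SARS (9.29), GRSF1 (9.24) and EFTUD1 (8.78). TAF2, CDC20 and EFTUD1 rest on 1 guide each. TAF2 was lower against T0 at the score of 7, while PITRM1, EEF1E1, SARS, GRSF1 and EFTUD1 had negative values that did not reach it. EFTUD1 came to a score of 6.57 after the trend with growth was removed.

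At a score of 7 or more, 443 of 18817 genes were higher and 40 lower, against 26 of 18872 pseudogenes. A share of 91.7% of the calls was higher, and 75.8% (194 higher, 62 lower) after the trend with growth was removed. Across genes, the drug phenotype was negatively correlated with the growth phenotype (Pearson r -0.487; -0.350 in pseudogenes), and 259 of the higher calls changed sign against T0. At a Benjamini-Hochberg adjusted p under 0.05, 0 genes passed (smallest 0.100), while 1919 passed an unadjusted p under 0.05.

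The antifolate list (25 genes) had 4 members higher and 3 lower at the score of 7, and 5 higher and 4 lower adjusted over the list alone, with a median of 0.138 at percentile 29.1. After the growth trend was removed MTHFD1 did not keep the score of 7 (5.85). The mTORC1 list had MTOR, LAMTOR5, LAMTOR3, RPTOR, MIOS, LAMTOR4 and MLST8 higher; its median of 0.930 lay at percentile 89.5, and at 99.93 after the growth trend was removed, when 6 of the 7 calls kept the score of 7. Adjusted over the list alone, FLCN passed in place of LAMTOR4 among 7 higher members, and NPRL2, which restrains mTORC1, was lower. Mitochondrial complex I had a median of 2.27 (percentile 99.8, and 99.85 after removal of the trend), with 9 members higher at the score of 7 and 15 adjusted over the list alone. After removal its median was 0.929 and 1 of the 9 calls, NDUFAF1, kept the score of 7. The mitochondrial ribosome had a median of 2.99 (percentile 99.95) with 13 members higher at the score of 7 and 18 adjusted over the list alone; after removal of the trend its percentile was 67.4 and 0 of the 13 calls kept the score of 7, and for treated cells against T0 it was 0. ABC drug efflux transporters had a median of 1.62 (percentile 99.9, and 76.6 after removal), with ABCC11 (3.98) and ABCC4 (2.89) called higher and 1 member adjusted over the list alone. In base excision and single-strand break repair (percentile 49.3), XRCC1 was higher and POLB and APEX2 lower; adjusted over the list alone, XRCC1 and PARP1 were higher and APEX2 lower. XRCC1 came to a score of 6.20 after removal of the trend, and neither XRCC1 nor LAMTOR4 passes a score set to a 5% pseudogene rate. The gemcitabine pharmacology list (median 0.762, percentile 99.1) had SLC29A1 and NT5C lower by both criteria, including adjusted over the list alone. Mediator (median -0.0264, percentile 1.06) had MED10 and MED31 higher and MED12 and CCNC lower at the score of 7, and 1 higher and 3 lower adjusted over the list alone; after removal MED10 (6.43) and MED31 (2.16) did not keep the score of 7, and MED10 does not pass a score set to a 5% pseudogene rate. The proteasome stress response and chaperone list (median -0.261, percentile 1.86, and 9.17 after removal) had HSPA4 higher, a call that ended after removal (4.38), and 0 adjusted over the list alone. Nucleotide excision repair had a median of 0.248 (percentile 15.2, and 43.9 after removal). Its members GTF2H4 (6.59), ERCC2, GTF2H2, GTF2H1, ERCC3 and GTF2H3 were higher, all also adjusted over the list alone. After removal, 3 of these 6 calls kept the score of 7. Over all genes, 0 members of these lists passed.

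Romidepsin inhibits class I histone deacetylases. The lowest genes were CDKN1A, which codes for the cell cycle inhibitor p21 (-14.4 control SDs), FZR1, an activator of the anaphase-promoting complex (-12.2), NPRL2, which restrains mTORC1 (-9.98), and the cell cycle inhibitor gene CDKN2A (-9.32). CDC23, a subunit of that complex (-7.85), was also lower, on 2 guides. AMBRA1, which limits cyclin D (-7.38), the iron-sulfur cluster scaffold gene ISCU (-7.10), ZNF699 (-7.10) and THOC6 (-6.68) were also among the lowest. The near neighbour of NPRL2, CYB561D2, was called lower with it. The drug's own targets were not called: HDAC1 stood at -0.0553, HDAC2 at 0.256 and HDAC3 at 0.349. The efflux pump gene ABCB1 (-0.285) was not called either.

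Among the higher genes under romidepsin were MEAF6 (9.49) and EPC2 (5.69), both of the NuA4 acetyltransferase complex, and the translation initiation gene EIF4G2 (7.14). IMPDH2, of guanine nucleotide synthesis (10.4), MRPL34 (7.35), RPS27A (6.59) and SMC1A (6.56) were higher on 1 guide each. CLPB (6.01), FH of the citric acid cycle (5.73) and DPY30 of histone methylation (5.57) completed the 10, with MEMO1, the near neighbour of DPY30, called higher as well. IMPDH2, MRPL34, RPS27A, FH and DPY30 were lower against T0 at the score of 7, and SMC1A and CLPB had negative values that did not reach it. MRPL34, RPS27A, SMC1A and FH do not pass a score set to a 5% pseudogene rate, and RPS27A (6.31) and SMC1A (6.24) fall under the score of 7 after removal of the trend with growth.

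At a score of 7 or more, 108 of 18799 genes were higher and 83 lower, against 21 of 18876 pseudogenes; at a 5% pseudogene rate the counts were 50 and 38. At a Benjamini-Hochberg adjusted p under 0.05, 0 genes passed (smallest 0.231), while 1494 passed an unadjusted p under 0.05.

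The histone deacetylase complex list (35 genes) had 0 members called at the score of 7 and 0 adjusted over the list alone, with a median of -0.320 at percentile 7.97. ABC transporters (percentile 25.6) likewise had 0 by either criterion, including adjusted over the list alone. The highest list was nucleotide excision repair (median 1.38, above all 10000 random lists), where GTF2H4 (4.12), GTF2H2 (4.11), GTF2H1 (3.12) and GTF2H3 (2.95) of the shared transcription and repair factor TFIIH were higher, all but GTF2H2 also adjusted over the list alone. Those TFIIH genes were also called higher under pralatrexate, and GTF2H3 under gemcitabine. Under romidepsin, the G1/S list (percentile 94.7) had CDK6 higher and CDKN1A, FZR1 and CDKN2A lower, and 2 higher and 3 lower adjusted over the list alone. The mTORC1 list (percentile 87.1) had MLST8, MIOS and RPTOR higher and its inhibitors NPRL2 and TSC1 lower, with 5 higher and 2 lower adjusted over the list alone. GTF2H2 and RPTOR do not pass a score set to a 5% pseudogene rate. Cullin ligases (median -0.554, percentile 0.1) and the 20S proteasome (median 1.17, percentile 99.5) had 0 members called at the score of 7 and 0 adjusted over the list alone. Over all genes, 0 members of these lists passed.

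**Figure D2:**
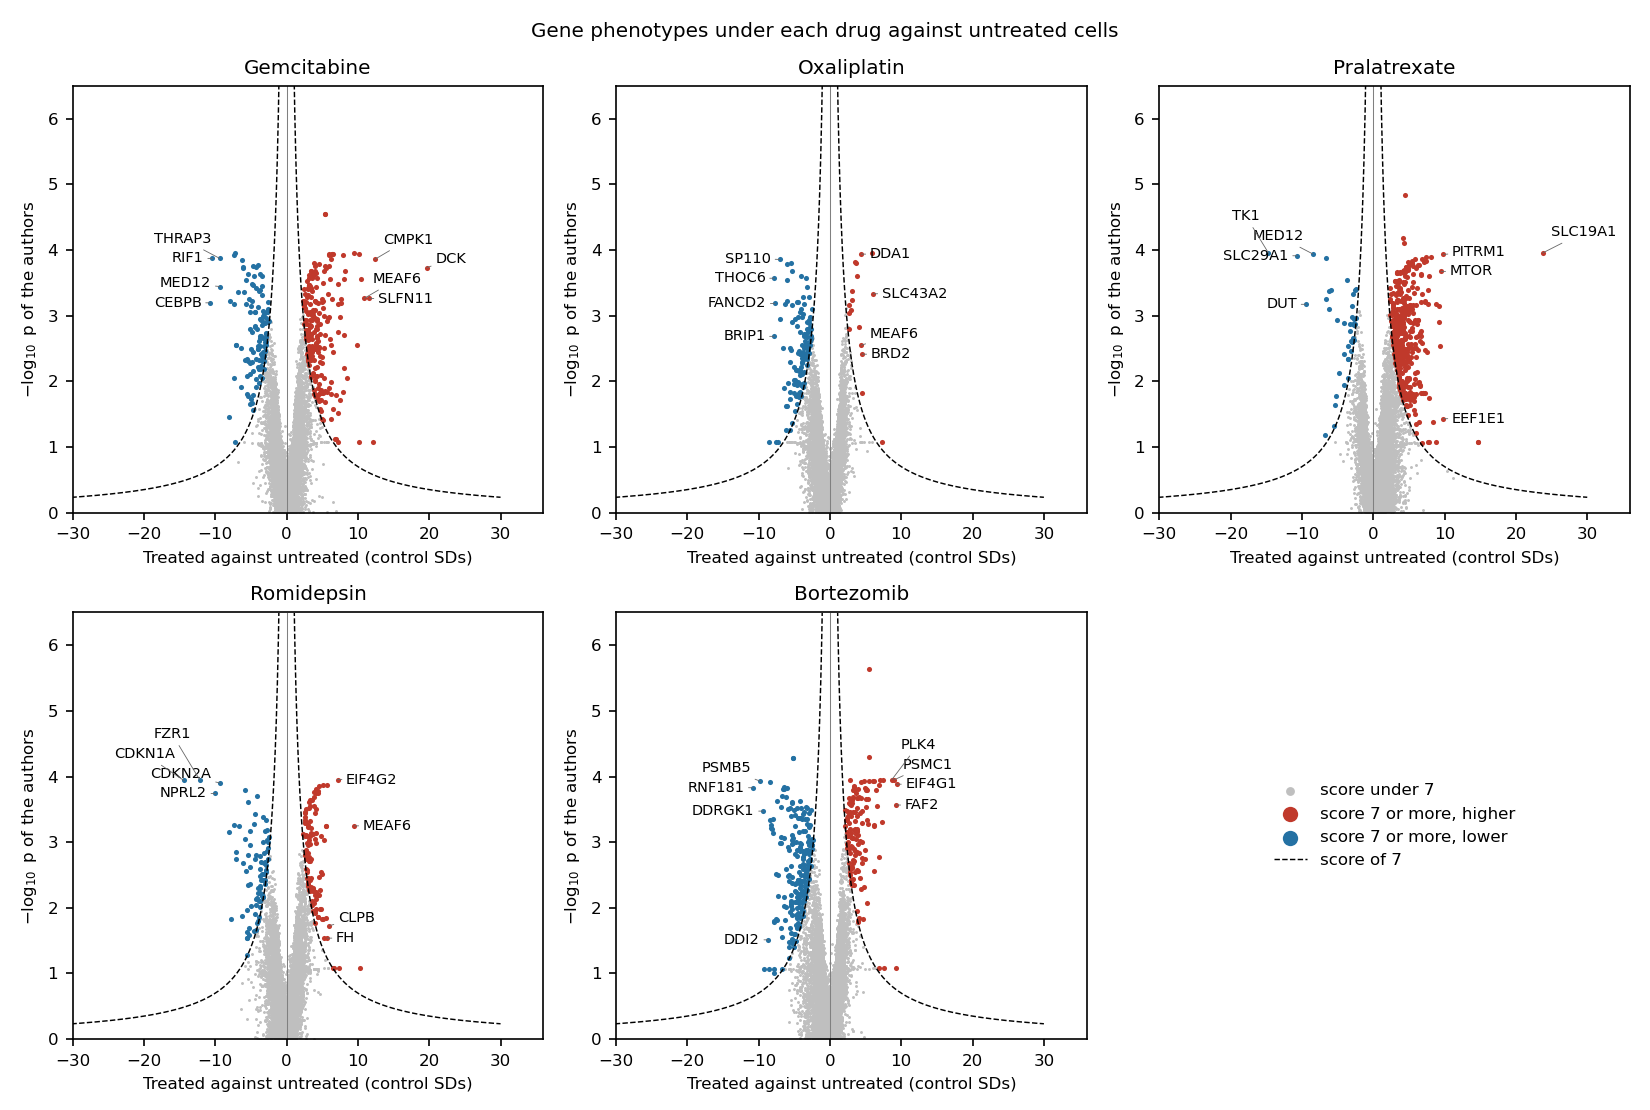
Each panel shows 1 drug, with the phenotype of every gene against untreated cells in control SDs on the x axis and the -log10 of the authors' p-value on the y axis; points past the dashed score of 7 are red where higher and blue where lower. DCK reaches 19.6 under gemcitabine, SLC19A1 23.8 under pralatrexate, CDKN1A -14.4 under romidepsin and PSMB5 -9.74 under bortezomib.

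Bortezomib inhibits the proteasome at its catalytic subunit beta 5. The 20S core and the 19S regulator of the proteasome went in opposite directions. PSMB5, which codes for the drug's target, was among the lowest genes (-9.74 control SDs), with the core subunit genes PSMB7 (-8.38), PSMB8 (-8.17), PSMA1 (-7.58, 2 guides) and PSMB4 (-6.74) and the assembly chaperone genes PSMG1 (-8.41) and POMP (-7.25). In the regulator, PSMC1 (9.01), PSMC2 (6.22), PSMD2 (6.13), PSMD7 (4.66, 2 guides), PSMD11 (4.56), PSMC5 (3.69) and PSMC3 (3.34) were higher. PSMD4, a ubiquitin receptor of the regulator, was lower (-6.34, 2 guides), and PSMD1 was not called (1.46). Against T0, PSMD2, PSMD7, PSMD11 and PSMC5 had negative values that did not reach the score of 7.

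NFE2L1, whose product induces proteasome genes, was lower under bortezomib (-5.87), as were DDI2, whose protease cleaves that product (-8.63), and NGLY1, which deglycosylates it (-7.86, unadjusted p 0.0970). RNF181, which codes for a ubiquitin ligase, was the lowest (-10.8), and DDRGK1 of UFMylation stood at -9.37. ALG9 (-8.32), HMGXB3 (-8.20), SNRPE (-9.19) and NSRP1 (-8.49) were lower, the last 2 on 1 guide each. The translation initiation gene EIF4G1 (9.39), FAF2, a cofactor of the segregase VCP (9.29), and NPLOC4, another VCP cofactor (5.13), were higher. So were the centriole kinase gene PLK4 (8.69), CNOT4 (7.42), the glycolytic gene PKM (7.33) and DPH5 of diphthamide synthesis (6.95). CENPI (9.33), RPP25L (7.56) and EIF2B3 (6.86) were higher on 1 guide each, and lower against T0 at the score of 7, on 5, 4 and 5 guides.

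At a Benjamini-Hochberg adjusted p under 0.05, 1 gene passed under bortezomib: RBM4, which codes for a splicing regulator, was higher (5.54 control SDs, 8 guides, adjusted p 0.0436). At a score of 7 or more, 135 of 18880 genes were higher and 221 lower, against 28 of 18878 pseudogenes. An unadjusted p under 0.05 was reached by 1778 genes.

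The 20S list (20 genes measured) had a median of -5.35, below all 10000 random lists, with 0 members higher and 14 lower both at the score of 7 and adjusted over the list alone. The 19S list had a median of 2.27, above all of them, with 7 members higher and 1 lower at the score of 7, and 10 higher and 1 lower adjusted over the list alone. The proteasome stress response and chaperone list (median 0.225, percentile 81.6) had NPLOC4 higher and DDI2, NGLY1 and NFE2L1 lower at the score of 7; adjusted over the list alone, HSPA4 was higher and NFE2L1 lower, and NPLOC4, DDI2 and NGLY1 did not pass. The unfolded protein and integrated stress response list (percentile 95.7) had EIF2B3, GCN1L1, SYVN1 and EIF2AK4 higher at the score of 7; adjusted over the list alone, DERL1 passed in place of EIF2B3 among 4 higher, and EIF2B4 was lower. Mediator had a median of -1.28, below all random lists, with 7 members lower at the score of 7 and 5 adjusted over the list alone. Mitochondrial complex I had a median of -1.57, also below all of them, with NDUFB10, NDUFB6 and NDUFA8 among the members lower and 3 members adjusted over the list alone. The mitochondrial ribosome (median -1.07, percentile 0.38) had 0 called and 0 adjusted over the list alone. The Fanconi anaemia list (median -1.06, percentile 0.07) had FANCD2 lower, and FANCD2 and FANCE adjusted over the list alone. Homologous recombination (median -0.615, percentile 2.41) had BRIP1 and XRCC2 lower, with BRIP1 adjusted over the list alone. Over all genes, 0 members of these lists passed. Higher calls in the 19S list were not confined to bortezomib. Under gemcitabine (percentile 96.2), PSMC5, PSMD2 and PSMC1 were higher, also adjusted over the list alone. Under romidepsin (percentile 88.1), PSMD7 and PSMD10 were higher, with 0 adjusted over the list alone. Under oxaliplatin PSMD8 was lower, and under pralatrexate 0 members were called.

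**Figure D3:**
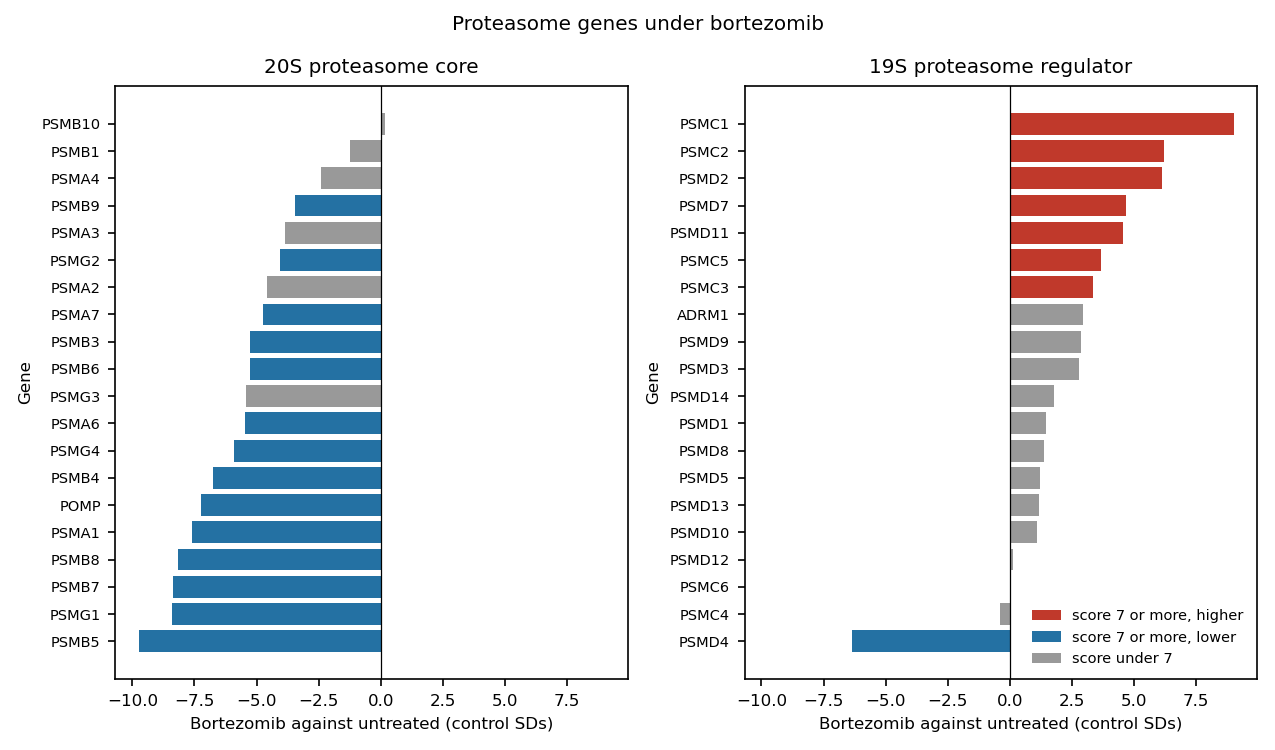
Phenotype of each measured gene of the 20S core list and of the 19S regulator list under bortezomib against untreated cells, in control SDs, 1 bar per gene. The 20S list has a median of -5.35 and the 19S list a median of 2.27, with PSMD4 (-6.34) the only member called against the direction of its list.

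The drugs were then compared with each other, to ask which genes were called the same way in several. MEAF6 and FAM136A were higher under all 5 drugs. ING3 and EPC2, which code for partners of MEAF6 in the NuA4 complex, were higher in 4 drugs each, as were DPH5 and EXOC2. GPI, BMS1, CCNT1 and PPCS were higher in 3. MED12, its kinase module partner CCNC and BCL2A1 were lower under all 5 drugs. THOC6, CEBPB and THRAP3 were lower in 4, and INO80E, SPOP, HEXIM1 and ZMYND8 in 3. At a score set to a 5% pseudogene rate, BCL2A1, DPH5, EXOC2 and GPI lose their romidepsin call and SPOP its pralatrexate call, which leaves BCL2A1 in 4 drugs, DPH5 and EXOC2 in 3, and GPI and SPOP in 2.

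At a score of 7 or more, 172 genes were higher and 67 lower in 2 or more drugs; after the growth trend was removed the counts were 100 and 75. Gemcitabine and pralatrexate shared 90 higher genes, where independent lists would share 5.37, and pralatrexate and romidepsin shared 51 (2.35 if independent). Oxaliplatin and bortezomib, which share no library, had 26 lower genes in common (1.33 if independent), and gemcitabine and bortezomib 26 higher (1.62) and 20 lower (1.37). Across genes, the Pearson r between drugs ran from 0.0453 for pralatrexate and bortezomib to 0.328 for gemcitabine and pralatrexate. For the latter pair the covariance was 0.560 over all genes and 0.169 over the fixed olfactory receptors, a difference of 0.390. Against all 366 olfactory receptor genes of the library the difference was 0.439. For oxaliplatin and romidepsin r was 0.261, with a covariance difference of 0.00349 against the fixed receptors and 0.170 against all of them. The difference was negative for oxaliplatin and pralatrexate (-0.141 and -0.0128) and, against the fixed receptors alone, for gemcitabine and bortezomib (-0.0485; 0.0741 against all), so its size depends on the receptors used. Drugs of screen 1 share their untreated library, so part of the excess between them may come from it; 1 library could not be split, and with no counts in the gene tables it was not simulated.

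**Figure D4:**
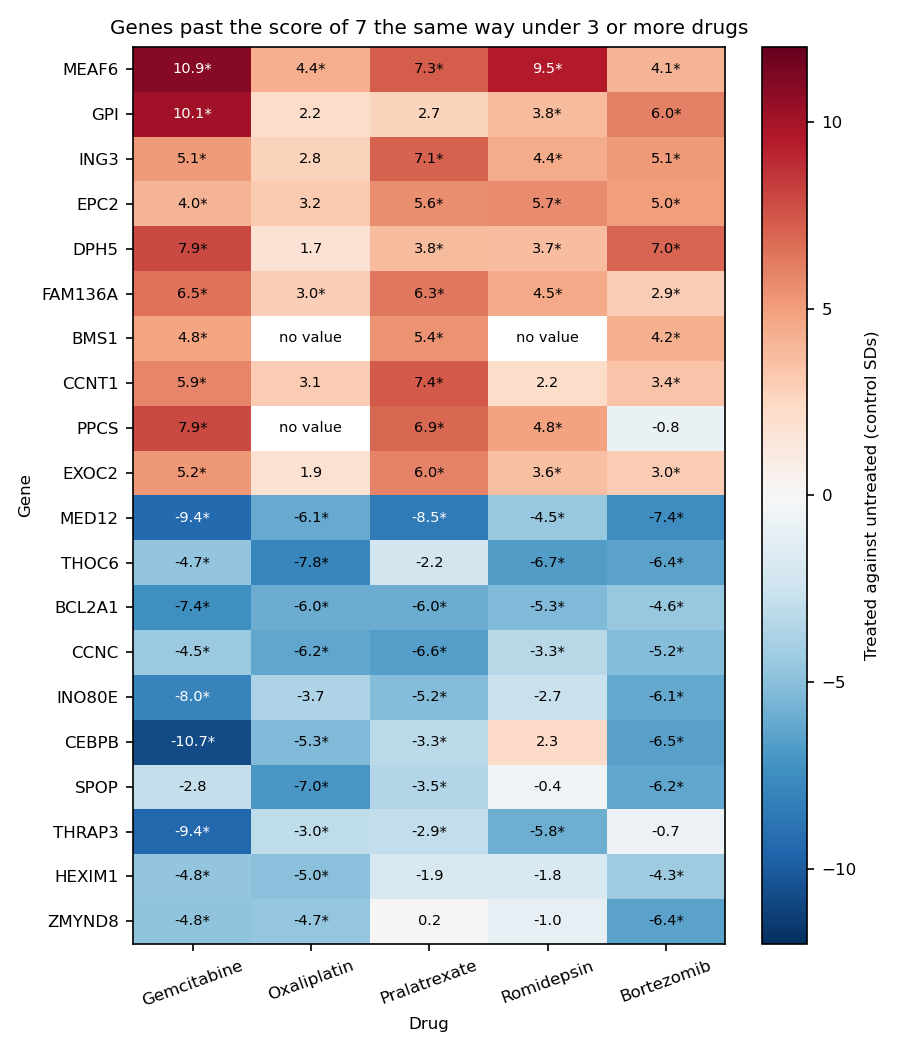
Heat map of phenotypes against untreated cells in control SDs for 20 genes called the same way in 3 or more drugs, with genes as lines, the 5 drugs as columns and an asterisk at a score of 7 or more. MEAF6 and FAM136A are higher, and MED12, BCL2A1 and CCNC lower, in all 5 columns.

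Of the remaining lists, apoptosis genes had BCL2A1 and BCL2L1 (-3.26) lower under oxaliplatin (percentile 33.9) and XIAP, BCL2A1 and BCL2L1 lower under bortezomib (percentile 6.30); adjusted over the list alone, 2 were higher and 2 lower under oxaliplatin and 1 was lower under bortezomib. The ALK and STAT3 list had STAT3 and PTPN1 higher under pralatrexate (percentile 15.8), the latter also adjusted over the list alone. After the growth trend was removed neither kept the score of 7 (2.88 and 4.02). Under gemcitabine (percentile 18.7), 1 member of this list was higher by both criteria, including adjusted over the list alone, and kept the score of 7 after removal. In iron, glutathione and thioredoxin, GPX4, which protects lipids from peroxidation, was higher under gemcitabine and pralatrexate (2 guides in each) and lower under bortezomib, with 0 members adjusted over the list alone in any drug; its calls under gemcitabine (5.99) and pralatrexate (4.42) ended after the growth trend was removed. In pyrimidine and purine synthesis, CTPS1 and ADSL were higher and HPRT1 lower under pralatrexate (percentile 67.8), with 2 higher and 2 lower adjusted over the list alone; after the growth trend was removed CTPS1 (2.73) and ADSL (2.76) no longer reached the score of 7, and ADSL does not pass a score set to a 5% pseudogene rate. The olfactory receptors, a control list of 62 genes, had 0 members called in any drug and 0 adjusted over the list alone, at percentiles 96.7, 92.0, 88.1, 94.3 and 7.72 in the order of the drugs above. Over all genes, 0 members of these lists passed. Of all 150 pairs of a list and a drug, 33 lay in the outer 2.5% on either side, where 7.5 would by chance for independent lists.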

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

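The tests that were chosen only after the result was seen are the test of the genes shared between drugs and the tests of the mitochondrial ribosome and of complex I, and the counts of opposite calls after removal of the growth trend were added late too; the tests of the higher calls under pralatrexate and of adjacent genes were set out before.

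Some genes passed the score of 7 in opposite directions under different drugs. The difference itself was not tested for any of them, since there is 1 library per drug. Beside each count stands the number that independent lists would give, and several counts are close to it. Gemcitabine and pralatrexate had 5 such genes (3.33 if independent): SLC29A1, TK1 and AFMID were higher under gemcitabine and lower under pralatrexate, and CTPS1 and ARID3A the reverse. SLC29A1 imports nucleosides, TK1 phosphorylates thymidine and CTPS1 makes cytidine triphosphate. Gemcitabine and bortezomib had 14 (3.45), among them GPX4, CCNA2, ELP2, ELP5 and PSMG4 (higher under gemcitabine) and EIF4G2 and EIF3H (lower). Pralatrexate and bortezomib had 20 (5.25), all of them higher under pralatrexate, among them the complex I genes NDUFB6 and NDUFB10, GPX4 and PSMG4. Romidepsin and bortezomib had 8 (1.76), with SUPT7L and KAT2A of the SAGA complex higher under romidepsin and CNOT4 lower. Gemcitabine and romidepsin had 6 (1.68), with CNOT4 higher under gemcitabine and EIF4G2 and SUPT7L lower. Oxaliplatin and romidepsin had 5 (0.714), with AMBRA1 and DDA1 higher under oxaliplatin and KAT2A and SUPT7L lower. Pralatrexate and romidepsin had 5 (2.13), with AMBRA1 and DDA1 higher under pralatrexate. Oxaliplatin and pralatrexate had 5 (2.69), with NDUFC1 and SUCLG1 lower under oxaliplatin. Gemcitabine and oxaliplatin had 3 (1.51), with FANCM higher under gemcitabine, and oxaliplatin and bortezomib had 1 (0.985), RFX1.

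After removal of the growth trend, the genes that kept both calls numbered 5 of 20 for pralatrexate and bortezomib, where NDUFB6, NDUFB10, GPX4 and PSMG4 lost their pralatrexate call. They numbered 0 of 5 for oxaliplatin and pralatrexate and 3 of 5 for gemcitabine and pralatrexate, where CTPS1 and ARID3A lost theirs. For gemcitabine and bortezomib 12 of 14 kept both, without GPX4, and for romidepsin and bortezomib 5 of 8, without KAT2A. For oxaliplatin and romidepsin, and for pralatrexate and romidepsin, 3 of 5 did. The 6, 3 and 1 genes of the remaining pairs kept both.

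TK1 and AFMID, which made the same opposite calls, are neighbours on the chromosome. Guides at a close promoter that act on both genes are a candidate explanation for such pairs. Among adjacent pairs with at least 1 call, both genes were called the same way in 35 of 811 pairs that lie 1000 bases or less apart (4.32%, 95% Clopper-Pearson interval 3.02% to 5.95%). Among pairs 10000 bases or more apart the count was 11 of 1453 (0.757%, 0.379% to 1.35%), a ratio of 5.70, in line with that explanation. A pair was counted once per drug, so a pair called under several drugs, such as TK1 and AFMID, entered more than once. The intervals treat these counts as independent, although the drugs of screen 1 share an untreated library, and are likely too narrow. Genes that lie close together may also share a function, which was not tested. Some neighbours may have been given the same guides, since NOP10 and NUTM1 had identical growth values in both screens. Such pairs would be called together by design of the library. The ratio cannot tell them from pairs with guides of their own.

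Genes called the same way in 2 or more drugs of screen 1 numbered 180, with 135 higher and 45 lower. Chance error of the untreated library that these drugs share would leave their sign under bortezomib, which has its own untreated library, at the level of growth-matched genes. Under bortezomib, 115 (63.9%) had the same sign, above the highest of the random lists (62.8%; 95% of them lay between 42.2% and 56.7%), and 36 were called the same way. As far as matching on growth deciles holds, this argues against the shared library as the whole cause. Part of the excess may still come from that library. The lowest growth decile spans a wide range, and the share was not recomputed after removal of the growth trend. A response common to several drugs, or to slower growth in treated cultures, stays open and was not tested.

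Higher calls under pralatrexate outnumber lower ones, and a trend of the drug phenotype with growth is a candidate explanation. After the trend was removed, 42.9% of the higher calls (190 of 443) stayed past the score of 7, between the bounds of 25% and 75% set out before. The part of the trend in the excess therefore cannot be told apart from that of other causes. The removal changed the phenotype and not the authors' p-value, so the score was corrected only in part and the share kept may be too high. For the mitochondrial ribosome the test was replaced after both results had been seen. Matching on growth deciles left its median at percentile 99.95, but after the trend was removed it lay at 67.4 (median 0.193), which is consistent with the trend. For complex I the same removal left the median at percentile 99.85 (0.929), which argues against the trend as the whole cause of the shift of the list, while 1 of its 9 calls kept the score of 7. Pseudogenes, which target no gene, had a correlation with growth of -0.350 beside -0.487 in genes, so part of the trend may come from the untreated library that enters both phenotypes; this was not tested.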

How the results depend on the processing

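The alternatives applied to counts at the score of 7, to opposite calls, to lists after removal of the growth trend and to the named genes were chosen only after the data had been seen, except an adjusted p under 0.01 with the score of 7 for the named genes; the others were planned. The cause was not tested for any change given here, except where the setting tests fewer genes. Counts are higher then lower, and drugs are in the order gemcitabine, oxaliplatin, pralatrexate, romidepsin and bortezomib.

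No paired analysis was possible because each group has 1 library. Another summary of the phenotype was not run, as the gene tables hold the 1 average.

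Counts at an adjusted p under 0.05 were 0 and 0 in the first 4 drugs and 1 and 0 under bortezomib. At the score of 7 they were 233 and 123, 17 and 118, 443 and 40, 108 and 83, and 135 and 221. At a score set to a 5% pseudogene rate they were 226 and 121, 17 and 109, 426 and 39, 50 and 38, and 124 and 210. An adjusted p for treated against T0, a different quantity that includes growth, gave 50 and 601, 4 and 262, 3 and 64, 9 and 288, and 62 and 726. For bortezomib, an adjusted p under 0.10 gave 66 and 43. RBM4 was lost, leaving 0, at an adjusted p under 0.01, with p times the number of promoters and over only genes with the usual number of guides, a setting that drops it. The other adjusted-p counts under these settings and with a minimum of 2 control SDs added did not move. Centring and removal of the growth trend change the phenotype and not the authors' p-value. Apart from a change of sign they could not move these counts, so they do not test them.

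The score of 7 for treated against T0 gave 56 and 1217, 9 and 1004, 46 and 684, 20 and 958, and 49 and 1232. Only genes with 5 or more guides left 154 higher under gemcitabine and 251 under pralatrexate. Only genes with no growth call left 117 higher under gemcitabine, 10 under oxaliplatin, 175 under pralatrexate, 51 under romidepsin, and 51 higher and 136 lower under bortezomib; both settings test fewer genes. Centring on the median gene gave 28 higher under oxaliplatin. Removing the growth trend gave 32 higher under oxaliplatin and 194 and 62 under pralatrexate. The other counts under these settings, with p times the number of promoters and with 1 gene kept per group of adjacent calls, stayed within 1.5 times.

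Of the higher calls, removing the growth trend kept 196 of 233, 17 of 17, 190 of 443, 87 of 108 and 133 of 135. Of the lower calls it kept 120 of 123, 98 of 118, 38 of 40, 75 of 83 and 215 of 221.

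For growth, an adjusted p under 0.01 left 0 higher and 0 lower in screen 1 and 0 higher and 724 lower in screen 2. The score of 7 gave 1587 lower in screen 1 and 2 higher in screen 2. At an adjusted p there was no overlap between drugs (0 genes), and the score of 7 gave 239 genes shared by 2 or more. For the naming rule, the score of 7 gave 127 of the 136 pairs of gene and drug and an adjusted p under 0.01 with the score of 7 gave 0.

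Against T0, 25 of the named genes changed sign, with these scores. Under gemcitabine they were ICT1 (-13.4), MRPL22 (-58.8) and TIMM44 (-7.73). Under oxaliplatin they were SARS (-8.31) and HEATR1 (-9.87). Under pralatrexate they were TAF2 (-25.5), PITRM1 (-2.27), EEF1E1 (-0.0310), SARS (-3.67), GRSF1 (-0.355) and EFTUD1 (-6.53). Under romidepsin they were IMPDH2 (-27.9), MRPL34 (-51.9), RPS27A (-33.6), SMC1A (-2.42), CLPB (-1.17), FH (-10.4) and DPY30 (-9.40). Under bortezomib they were CENPI (-42.0), RPP25L (-35.5), EIF2B3 (-31.4), PSMC5 (-0.592), PSMD2 (-1.59), PSMD7 (-1.95) and PSMD11 (-0.856). Some of these genes rest on more guides against T0 than against untreated cells, such as MRPL22 under gemcitabine and CENPI under bortezomib (5 and 1 in both). Their change of sign need not come from the same guides. Of the other named genes, 14 kept their direction and no longer reached the score of 7, and 95 kept their side of it, with direction read for called genes only. Centring, and p times the number of promoters, left 135 on their side, and removing the growth trend 131.

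Of the 150 pairs of a list and a drug, 51 lay past the percentiles among unmatched random lists, 40 against T0 and 41 after removal of the growth trend, beside 33. The mitochondrial ribosome under pralatrexate reversed against T0, to percentile 0. The correlation of gemcitabine and pralatrexate was 0.274 by Spearman, 0.243 over genes with no growth call and 0.237 after removal of the growth trend, beside 0.328.

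Depth per library is unknown, so what it limits could not be computed.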

Other observations

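Every list in this part was chosen only after the top genes of a drug had been seen, and those seen genes were left out of the tests; the percentiles after removal of the growth trend were added later still.

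Each hypothesis was that the rest of a complex or pathway goes the way of its seen genes, and its test was the percentile of the median of the other members among growth-matched random lists. Under bortezomib, the other 5 genes of diphthamide synthesis, which modifies elongation factor 2, had a median of 3.67 control SDs at percentile 100 (100 after removal of the growth trend), and DPH1, DPH6 and DNAJC24 were called higher while DPH3 (0.455) and DPH7 (0.330) were not. The other 14 glycolysis genes had a median of 1.04 at percentile 99.97 (99.92), with PFKP and TPI1 called higher. The other 10 genes of centriole duplication had a median of 1.43 at percentile 99.73 (98.12), with CEP152 and TUBE1 called. The other 7 genes of UFMylation, which attaches a ubiquitin-like protein at the endoplasmic reticulum, had a median of -1.53 at percentile 0.22 (0.285), with UFL1 called lower. These results are consistent with each of those pathways moving together in this library. The other 15 genes of the translation factors eIF3 and eIF4F had a median of -0.0604 at percentile 41.6 (37.7), which argues against a common direction, although EIF4B and EIF4H were called higher.

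Under romidepsin, the other 10 measured members of the NuA4 complex had a median of 1.40 at percentile 98.6, with DMAP1, MRGBP and BRD8 called higher, in line with the hypothesis; after removal of the growth trend the percentile was 97.37, just short of the highest 2.5%. Under pralatrexate the same members had a median of 1.60 at percentile 75.8 (95.88 after removal), which leaves the hypothesis open, with DMAP1, BRD8 and RUVBL1 called. Under oxaliplatin, the other 16 members of the SAGA complex had a median of -1.14 at percentile 0.49 (0.42), with TADA1 called lower, in line with the complex moving together in this library.

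Calls were also counted by the number of guides. Genes with 1 or 2 guides passed the score of 7 in 3.70%, 1.36%, 8.09%, 1.97% and 8.56% of cases under gemcitabine, oxaliplatin, pralatrexate, romidepsin and bortezomib. Genes with 5 or more guides passed in 1.62%, 0.632%, 1.88%, 0.966% and 1.71%. Pseudogenes with 5 or more guides passed in 0.118%, 0.0838%, 0.191%, 0.179% and 0.193%. For pseudogenes with 1 or 2 guides the shares were 0.0807%, 0%, 0.164%, 0% and 0.0879%. In untreated cells against T0, the genes with 1 or 2 guides in the gemcitabine comparison had a median growth phenotype of -10.9. Those in the bortezomib comparison had -17.6.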
